A study of Homo sapiens with 6 samples.

How the data were processed

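AGS gastric adenocarcinoma cells, grown per the labels in DMEM-F12 with 10% FBS, were treated with 5 µM doxycycline or 0.01% DMSO, and RNA was taken after 48 h. Labelled sense cDNA was made from 500 ng of total RNA with the Ambion WT Expression kit and measured on the Affymetrix Human Transcriptome Array 2.0, per the labels' protocols. Groups and replicate numbers were taken from the sample labels, which gave 3 arrays with DMSO and 3 with doxycycline.

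The deposited values were made by the authors with RMA in Affymetrix Expression Console 1.4.1.46, per the submitters' processing notes. RMA names a background correction, a quantile normalization between arrays and a median polish over the probes of a feature, and its values are on a log2 scale. The log base is not stated in the file, and the deposited values, given to 2 decimals, ran from 1.94 to 19.93 and were taken as log2. Of them, 4423 lie above 16, which a 16-bit scanner cannot give directly, so a step that stretches the scale may be included and was not given in the sources used here. Differences are therefore stated on the deposited scale and may be larger than those of plain RMA values. Medians of the 6 arrays lay between 4.07 and 4.12. Detection calls were not used here, and group means are given for most genes described below with a mean under about 5, near that level. The genome build of the array's annotation was not given in the sources used here, so no coordinates are printed.

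Features were named through the platform's annotation table, whose symbols were updated by gene identifier, symbol or synonym against the RefSeq gene table of GRCh38.p14, which was used for names only. Of 70523 features, 23781 had 1 gene symbol, 1543 had several and 45199 had none in the table. Names came from the gene identifier for 21497 features, the symbol for 1974 and a synonym for 306, and 4 were kept as given. A gene was represented by its brightest feature over all 6 arrays, which left 22411 genes, 17154 of them protein-coding. Of the 528 genes with more than 1 feature, 1 had features called in opposite directions and 64 had some called and some not. Among the genes named by the rule given below, 2 had several features, and neither had opposite calls. Genes named beyond that rule, such as VARS1 with 7 features, were not part of this check. Features with several symbols or none were left out of the gene test.

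Genes were tested with limma 3.58.1 in R 4.3.3, with lmFit on treatment and eBayes with a mean-variance trend, without a block, on all 6 arrays. Every adjusted p of a gene is limma's with the Benjamini-Hochberg adjustment over the genes tested, two-sided, with a threshold of 0.05. Errors of changes are moderated standard errors, and changes are doxycycline minus DMSO. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists with at least 5 measured members. The same test with an estimated correlation and fry were alternatives. With an estimated correlation, camera also takes its degrees of freedom from the arrays and not from the genes. With 3 arrays per group it then has little power. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.

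The design, the tests, the 34 lists with their 845 members and the rule for named genes were set before the data were examined. Of the members, 726 were measured and 119 were not, among them the 13 mRNAs encoded in mitochondria, so that list had no test. The lists cover the respiratory chain (nuclear and mitochondrial genes), mitochondrial ribosomal proteins, mitochondrial chaperones and proteases, ATF4 and integrated stress response targets, serine and one-carbon metabolism, aminoacyl-tRNA synthetases and the endoplasmic reticulum unfolded protein response. They also cover glycolysis, hypoxia, iron, metallothioneins, NRF2 targets, heat shock, cholesterol synthesis, fatty acid metabolism, mitosis, DNA replication, histones, p53 targets, the BCL2 family, and autophagy and lysosome genes. The rest are metalloproteinases, protease-activated receptors and coagulation proteases, epithelial-mesenchymal transition, inflammatory cytokines, interferon response, immediate-early genes, Wnt targets, gastric and intestinal markers, stem-cell markers, cytosolic ribosomal proteins, and markers of fibroblasts and of leukocytes. Several genes stand on more than 1 list.

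Named genes were the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members per list with the smallest p. Small RNA genes, clone names and pseudogenes were replaced by the next gene, which passed over MIR373, FABP5P7 and FABP5P1. Some further members, mostly of lists in which 5 or fewer moved one way, were named after their values were seen.

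The scripts were tested on simulated data with the real genes' means, with spreads moved toward the median spread and with genes drawn independently. In 10 simulations of 3 arrays against 3 over 22411 genes with 200 changed, the test recovered 49.8% of genes changed by 0.5 log2 units, 96.6% at 1, 99.6% at 2 and 100% at 4. On average 6.69% of the calls were false, above the nominal rate. The 200 changed genes are far fewer than the 6070 called in the data. The adjustment depends on that share, so these rates may not carry over to the real comparison. Without changes at most 0 genes and 0 lists passed, and a list of 18 genes shifted by 0.5 log2 units passed in 10 of 10 simulations. Because genes were drawn independently, the 0 lists do not show how camera behaves where genes vary together.

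Alternatives set beforehand were other variance models, array weights, 2 other scalings, a filter on dim genes, all features, the mean of a gene's features, the replicate number as a block, stricter thresholds, other set tests and each array left out in turn. Leaving out the 2 arrays that stood apart, treating them as a block, and testing protein-coding genes alone were added after the data were seen.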

Results

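Gene expression was measured in AGS cells, an established human gastric adenocarcinoma line. The cells were treated for 48 h with 5 µM doxycycline or with 0.01% DMSO, which the labels name the control. No DMSO percentage was recorded here for the doxycycline arrays. Doxycycline is a tetracycline antibiotic known to block protein synthesis on bacterial and mitochondrial ribosomes. Each group held 3 arrays, which the labels name biological replicates 1 to 3, and each array was hybridised with material from 500 ng of total RNA with a RIN of 10. Whether the replicates came from separate experiments or from wells of 1 plate was not given in the sources used here, so the p-values may measure only the spread between wells. The Human Transcriptome Array 2.0 gave values for 70523 features, of which 22411 genes with 1 feature each were tested. With 3 arrays per group, the number of arrays limits the precision, and the median standard error of a change was 0.09 on the log2 scale over all tested genes. It was 0.13 for genes with a mean signal of 8 or more.

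The arrays separated by treatment. Pearson correlations over the tested genes, which are not independent replicates, ranged from 0.994 to 0.998 between arrays of 1 group and from 0.971 to 0.978 between arrays of different groups. The first principal component held 79.7% of the variance and separated the groups. The second held 12.1% and set DMSO replicate 3 and doxycycline replicate 1 apart from the other 4 arrays. Poly-A control transcripts added to the RNA were 0.27 to 0.60 log2 units higher on the doxycycline arrays and hybridisation controls lower by 0.20 to 0.33, and none of these 8 control features passed the test (limma, adjusted p between 0.25 and 0.69).

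**Figure D1:**
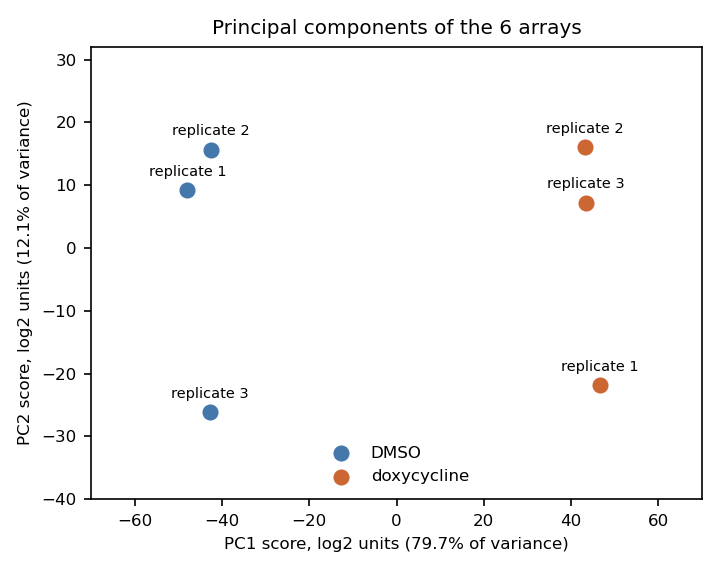
Principal component scores (log2 units) of the 6 arrays over the tested genes, with 1 point per array coloured by treatment. The first component (79.7% of the variance) separates doxycycline from DMSO and the second (12.1%) sets DMSO replicate 3 and doxycycline replicate 1 apart.

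The comparison asked how the transcript profile of these cells changed with doxycycline. With doxycycline, 23 of 30 targets of the transcription factor ATF4 rose and 0 fell, and of 21 genes of the endoplasmic reticulum unfolded protein response 14 rose and 2 fell. Among them, SLC7A11, the cystine transporter subunit, rose by 6.62 ± 0.10 log2 units (SE, n = 3 per group), DDIT4, an inhibitor of mTORC1 signalling, by 6.21 ± 0.18, and HERPUD1, an endoplasmic reticulum stress protein, by 5.52 ± 0.12. DNA replication genes fell in 31 of 32 and mitotic genes in 31 of 31, and 15 of 19 cholesterol synthesis genes, 21 of 39 nuclear genes of the respiratory chain and 27 of 46 genes of the mitochondrial ribosome fell. These 7 lists passed camera with a preset correlation and none passed with an estimated one (adjusted p from 0.178 to 0.37). LGR5, a Wnt target and intestinal stem-cell marker, fell by 4.66 ± 0.11 log2 units.

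Of the 22411 genes, 6070 (27.1%) changed at an adjusted p under 0.05 (limma), and 3106 rose while 2964 fell. At least a 2-fold change was found for 1874 of them, 919 higher and 955 lower with doxycycline. The 3 doxycycline values all lay on 1 side of the 3 DMSO values for 8814 genes (39.3%), where chance gives 10%. Changes are on the scale of the deposited values, 697 features of which had means above 16, the log2 ceiling of a 16-bit scanner. An unstated step may thus have stretched that scale, and folds can exceed those of other processing.

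The 12 largest rises that the naming rule admits were SLC7A11, DDIT4, CHAC1, DDIT3, TCP11L2, HERPUD1, UPP1, SLFN5, ARRDC3, SLC16A4, LAMP3 and ASNS, from 6.62 down to 4.32 log2 units. CHAC1, which degrades glutathione, rose by 5.68 ± 0.21, and DDIT3, the transcription factor CHOP, rose by 5.63 ± 0.17 from a DMSO mean of 4.20, close to the median of all features of 4.09. UPP1, uridine phosphorylase, rose by 4.86 ± 0.21, and ASNS, asparagine synthetase, rose by 4.32 ± 0.17. SLC16A4, a monocarboxylate transporter family member, rose by 4.49 ± 0.23, and LAMP3, a lysosomal membrane protein, by 4.48 ± 0.18. TCP11L2 rose by 5.59 ± 0.10, SLFN5 by 4.77 ± 0.12 and ARRDC3 by 4.51 ± 0.21. The DMSO means of LAMP3 and UPP1, 4.49 and 4.96, lay near the median of all features. Levels there were not tested against background, so the rises of DDIT3, LAMP3 and UPP1 may be lower bounds, and their order among the rises is not settled. All 12 had adjusted p-values of 4.23e-05 or less (limma).

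The 12 largest falls were PSG11, PSG1, PSG6, FAM111B, REG4, LGR5, FGA, CDCA7, ARRB1, GDA, LYZ and KIF20A, from -6.89 to -3.58 log2 units. PSG11, PSG1 and PSG6 encode pregnancy-specific glycoproteins and fell by 6.89 ± 0.20, 6.16 ± 0.21 and 5.69 ± 0.25, to means between 3.99 and 4.54, near the median of all features. These genes are near-identical copies of each other, so which copy a probe read is uncertain. FAM111B fell by 5.13 ± 0.21, FGA, the fibrinogen alpha chain, by 4.51 ± 0.36, and CDCA7, a cell-cycle gene, by 4.01 ± 0.25. ARRB1, beta-arrestin 1, fell by 3.77 ± 0.10, GDA, guanine deaminase, by 3.67 ± 0.09, LYZ, lysozyme, by 3.60 ± 0.25, and KIF20A, a mitotic kinesin, by 3.58 ± 0.20. REG4, a secreted lectin of gastrointestinal epithelium, fell by 4.73 ± 0.14 to a mean of 3.803, and FGA fell to a mean of 4.01. Levels this near the median of all features were not tested against background, so the falls of the PSG genes, REG4 and FGA may be lower bounds, and their order among the falls is not settled. The highest adjusted p among the 12 was 0.00021, for FGA (limma).

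**Figure D2:**
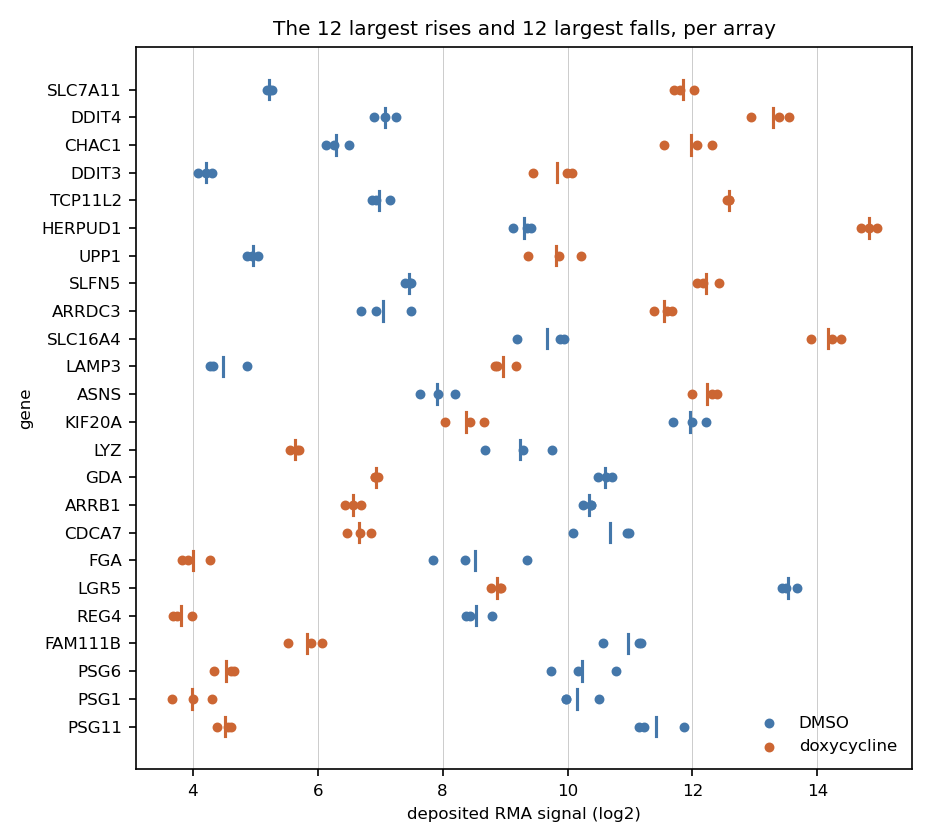
Deposited RMA signal (log2) of the 12 genes with the largest rises (top) and the 12 with the largest falls (bottom), with 1 point per array, 3 per group, and a vertical bar at each group's mean. The groups do not overlap for any of these genes, which the naming rule required, and changes run from 6.62 for SLC7A11 to -6.89 for PSG11.

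Of the 33 gene lists with measured members that were fixed before the data were examined, 20 passed camera with a preset correlation between genes of 0.01, 8 upward and 12 downward. None of the 20 passed with a correlation estimated from the data, where adjusted p-values ran from 0.178 to 0.598, so each is given below with both p-values, and 27 lists passed fry's directional test. The counts of members rest on the limma test of each gene. Up to 4 members per list were named by the smallest p, and members named beyond these, mostly where 5 or fewer moved one way, were chosen after their values were seen.

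Among 30 measured targets of ATF4 and the integrated stress response, 23 rose and 0 fell, with 7 not passing (adjusted over the list alone, 24 rose and 1 fell). The median was 2.35 log2 units (camera adjusted p = 4.84e-17, and adjusted p = 0.178 with an estimated correlation). The 7 without a call had means near the median of all features in both groups. Among them were TRIB3 (DMSO 4.38, doxycycline 4.55) and FGF21 (3.40 and 3.48). Levels there were not tested against background, so these 7 may include genes that were not expressed. SLC7A11, DDIT4 and DDIT3 led the list, and SLC1A4, a neutral amino acid transporter, rose by 2.35 ± 0.07. Of 21 genes of the endoplasmic reticulum unfolded protein response, 14 rose and 2 fell, with the same counts adjusted over the list alone (median 1.22, adjusted p = 4.64e-06, and adjusted p = 0.178 with an estimated correlation). DNAJC3, a co-chaperone, rose by 2.08 ± 0.09, EDEM1, of endoplasmic reticulum-associated degradation, by 2.63 ± 0.12, and ERN1, the stress sensor IRE1, by 2.82 ± 0.14. The 2 that fell were the chaperone CALR, by 0.61 ± 0.13, and PDIA4, a disulfide isomerase, by 0.50 ± 0.13. The call of PDIA4 ended without DMSO replicate 1 or 2 (-0.44 and -0.45, adjusted p = 0.109 and 0.0963) and without doxycycline replicate 1 or 3 (-0.42 and -0.49, adjusted p = 0.0756 and 0.104). Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in 13 and fell in 4 of 19 genes (13 and 5 adjusted over the list alone). Their median was 1.04 (adjusted p = 0.000319, and adjusted p = 0.266 with an estimated correlation). WARS1 rose by 2.95 ± 0.09 and AARS1 by 2.44 ± 0.11, whereas VARS1 fell by 0.93 ± 0.07, HARS1 by 1.02 ± 0.12, QARS1 by 0.65 ± 0.14 and FARSB by 0.63 ± 0.18. Without DMSO replicate 1 QARS1 had -0.61 (adjusted p = 0.0641), and the call of FARSB outlasted only the loss of DMSO replicate 3, with -0.72 to -0.50 and adjusted p between 0.0722 and 0.135 without each of the other 5 arrays.

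Autophagy and lysosome genes rose in 13 and fell in 1 of 24 (14 and 1 adjusted over the list alone), with a median of 0.74 (adjusted p = 1.09e-05, and adjusted p = 0.37 with an estimated correlation). WIPI1 rose by 3.81 ± 0.14, MAP1LC3B, the autophagosome protein LC3B, by 3.14 ± 0.21, and SQSTM1, the cargo receptor p62, by 2.11 ± 0.10, and GLA, a lysosomal galactosidase, fell by 1.31 ± 0.19. Metallothioneins with the zinc exporter SLC30A1 rose in 9 of 11 genes and fell in 0 (11 and 0 adjusted over the list alone). Their median was 1.12 (adjusted p = 3.13e-06, and adjusted p = 0.187 with an estimated correlation). MT2A rose by 3.66 ± 0.31 and SLC30A1 by 1.82 ± 0.25, and metallothionein genes are similar enough that probes may not tell them apart. Immediate-early genes rose in 16 and fell in 1 of 24, also adjusted over the list alone (median 0.60, adjusted p = 2.53e-07, and adjusted p = 0.37 with an estimated correlation). The transcription factors EGR1 and KLF6 rose by 3.74 ± 0.09 and 2.01 ± 0.10, PHLDA1 rose by 2.66 ± 0.16, and MYC fell by 0.45 ± 0.13. The call of MYC ended without DMSO replicate 1 or 2 (-0.43 and -0.39, adjusted p = 0.131 and 0.129) and without doxycycline replicate 1 or 3 (-0.38 and -0.43, adjusted p = 0.103 and 0.14).

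Of 18 hypoxia response genes, 9 rose and 2 fell, also adjusted over the list alone, with a median of 0.40 (adjusted p = 0.00395, and adjusted p = 0.37 with an estimated correlation). VEGFA, the angiogenic growth factor, rose by 3.11 ± 0.09 and NDRG1 by 3.32 ± 0.12, whereas the prolyl hydroxylases EGLN3 and EGLN1 fell by 3.26 ± 0.17 and 0.72 ± 0.10. BCL2 family and death receptor genes rose in 11 and fell in 1 of 21, also adjusted over the list alone, with a median of 0.33 (adjusted p = 0.00386, and adjusted p = 0.37 with an estimated correlation). The risen members do opposing things: TNFRSF10B, a death receptor, rose by 1.81 ± 0.10 and PMAIP1, the pro-apoptotic NOXA, by 1.96 ± 0.22, and XIAP, an inhibitor of caspases, by 1.43 ± 0.10. BID, a pro-apoptotic protein, fell from a mean of 7.60 to 6.10.

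All 31 mitotic cell cycle genes fell, also adjusted over the list alone, with a median of -2.03 (adjusted p = 4.33e-23, and adjusted p = 0.178 with an estimated correlation). The cyclins CCNF and CCNA2 fell by 2.94 ± 0.10 and 2.61 ± 0.11, and the kinesin KIF11 by 1.94 ± 0.09. BUB1, a spindle checkpoint kinase, fell by 2.25 ± 0.10. DNA replication genes fell in 31 of 32 and rose in 0 (32 fell adjusted over the list alone), with a median of -1.81 (adjusted p = 2.48e-23, and adjusted p = 0.187 with an estimated correlation). POLA2, a subunit of DNA polymerase alpha, fell by 2.73 ± 0.08, CHAF1B by 2.30 ± 0.09 and CLSPN by 2.40 ± 0.10. Of 44 replication-dependent histone genes on the list, 20 were measured. Among these, 17 fell and 0 rose (18 fell adjusted over the list alone), with a median of -1.51 (camera adjusted p = 3.10e-09, and adjusted p = 0.304 with an estimated correlation). H2BC17 fell by 3.07 ± 0.16 and H2BC10 by 3.54 ± 0.29. Histone genes are similar copies whose probes may not tell them apart, and on the 2 arrays that stood apart their median lay 0.52 log2 units under the other arrays of the same group (a shared deviation of -0.52).

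Cholesterol synthesis genes fell in 15 of 19 and rose in 0 (16 fell adjusted over the list alone), with a median of -1.33 (adjusted p = 3.10e-09, and adjusted p = 0.304 with an estimated correlation). DHCR7, of the last step of the pathway, fell by 3.45 ± 0.10, HMGCS1 by 2.95 ± 0.13, and LSS and EBP by 2.00 ± 0.09 and 1.88 ± 0.09. Of 15 genes of fatty acid synthesis and oxidation, 6 fell and 0 rose (6 and 2 adjusted over the list alone), with a median of -0.39 (adjusted p = 0.0127, and adjusted p = 0.37 with an estimated correlation). FASN, ACLY and SCD, enzymes of synthesis, fell by 2.58 ± 0.12, 2.02 ± 0.09 and 0.84 ± 0.09, and HADHA, of oxidation, by 1.06 ± 0.12. Glycolysis genes fell in 12 and rose in 3 of 21 (14 and 3 adjusted over the list alone), with a median of -0.68 (adjusted p = 0.000171, and adjusted p = 0.304 with an estimated correlation). PGAM1 and LDHA fell by 2.22 ± 0.10 and 1.57 ± 0.10, whereas the glucose transporter SLC2A1 rose by 1.15 ± 0.13 and the hexokinases HK1 and HK2 by 0.78 ± 0.07 and 0.53 ± 0.11. The call of HK2 ended with the replicate number as a block (0.53, limma adjusted p = 0.0512).

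Nuclear genes for respiratory chain subunits fell in 21 of 39 and rose in 0 (24 fell adjusted over the list alone), with a median of -0.54 (adjusted p = 1.44e-08, and adjusted p = 0.37 with an estimated correlation). ATP5F1B and ATP5F1A, of ATP synthase, fell by 0.84 ± 0.08 and 1.31 ± 0.15, and CYC1 and UQCRC2, of complex III, by 1.44 ± 0.16 and 1.30 ± 0.15. Mitochondrial ribosomal protein genes fell in 27 and rose in 1 of 46 (30 and 2 adjusted over the list alone), with a median of -0.59 (adjusted p = 1.57e-08, and adjusted p = 0.37 with an estimated correlation). MRPL12 fell by 1.51 ± 0.09 and MRPS27 by 1.83 ± 0.11, and MRPS10 rose by 0.69 ± 0.13. Of 51 cytosolic ribosomal protein genes on the list, 33 were measured. Among these, 7 fell and 0 rose (6 fell adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.00279, and adjusted p = 0.598 with an estimated correlation). Fry did not call this list (adjusted p = 0.131). The median lay inside the range from -0.26 to 0.32 that holds 95% of lists matched on mean signal, and on the 2 arrays that stood apart the list deviated by -0.30, a larger size than that of its change. Those arrays are in different groups, so a deviation they share largely cancels in the change, and without them the median was also -0.25. RPS14 fell by 0.48 ± 0.08, RPS23 by 0.59 ± 0.13, RPL34 by 0.39 ± 0.09 and RPS6 by 0.48 ± 0.12. Single arrays ended 3 of these calls while the changes stayed of similar size. RPS23 had a change of -0.55 without DMSO replicate 1 and -0.59 without doxycycline replicate 3 (adjusted p = 0.063 and 0.0575), and RPL34 one of -0.37 without doxycycline replicate 2 (adjusted p = 0.0668). RPS6 had -0.47, -0.46 and -0.53 without DMSO replicate 1, DMSO replicate 2 and doxycycline replicate 3 (adjusted p = 0.0761, 0.0671 and 0.0516). Heat shock response genes fell in 10 of 12 and rose in 0 (11 fell adjusted over the list alone), with a median of -1.11 (adjusted p = 8.40e-07, and adjusted p = 0.266 with an estimated correlation). The chaperones HSPA1A, DNAJA1 and HSP90AB1 fell by 2.53 ± 0.15, 1.78 ± 0.12 and 1.11 ± 0.08. The 13 mRNAs encoded in mitochondria formed a further list, of which 0 were measured under 1 gene symbol.

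Wnt/beta-catenin targets fell in 10 and rose in 1 of 19, also adjusted over the list alone, with a median of -0.30 (adjusted p = 0.00141, and adjusted p = 0.266 with an estimated correlation). LGR5 led the list, the secreted antagonist DKK1 fell by 2.85 ± 0.13 and AXIN2 fell by 1.80 ± 0.10, and CCND1, cyclin D1, rose by 0.89 ± 0.11. Gastric and intestinal differentiation markers fell in 11 and rose in 2 of 30 (11 and 3 adjusted over the list alone). Their median was -0.03 and their mean -0.56 (adjusted p = 0.0131, and adjusted p = 0.508 with an estimated correlation). Most markers without a call lay near the median of all features, among them MUC2, PGC and GKN1 (DMSO means 3.97, 3.55 and 3.59), unlike CEACAM5 (9.60). Levels there were not tested against background, so the median and the count of 30 may include genes that were not expressed. REG4 led the list, VIL1, villin, fell by 3.42 ± 0.16, CDH17 by 1.80 ± 0.14 and the transcription factor GATA4 by 1.26 ± 0.09, whereas TFF1 and MUC1 rose by 1.69 ± 0.23 and 0.70 ± 0.12.

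**Figure D3:**
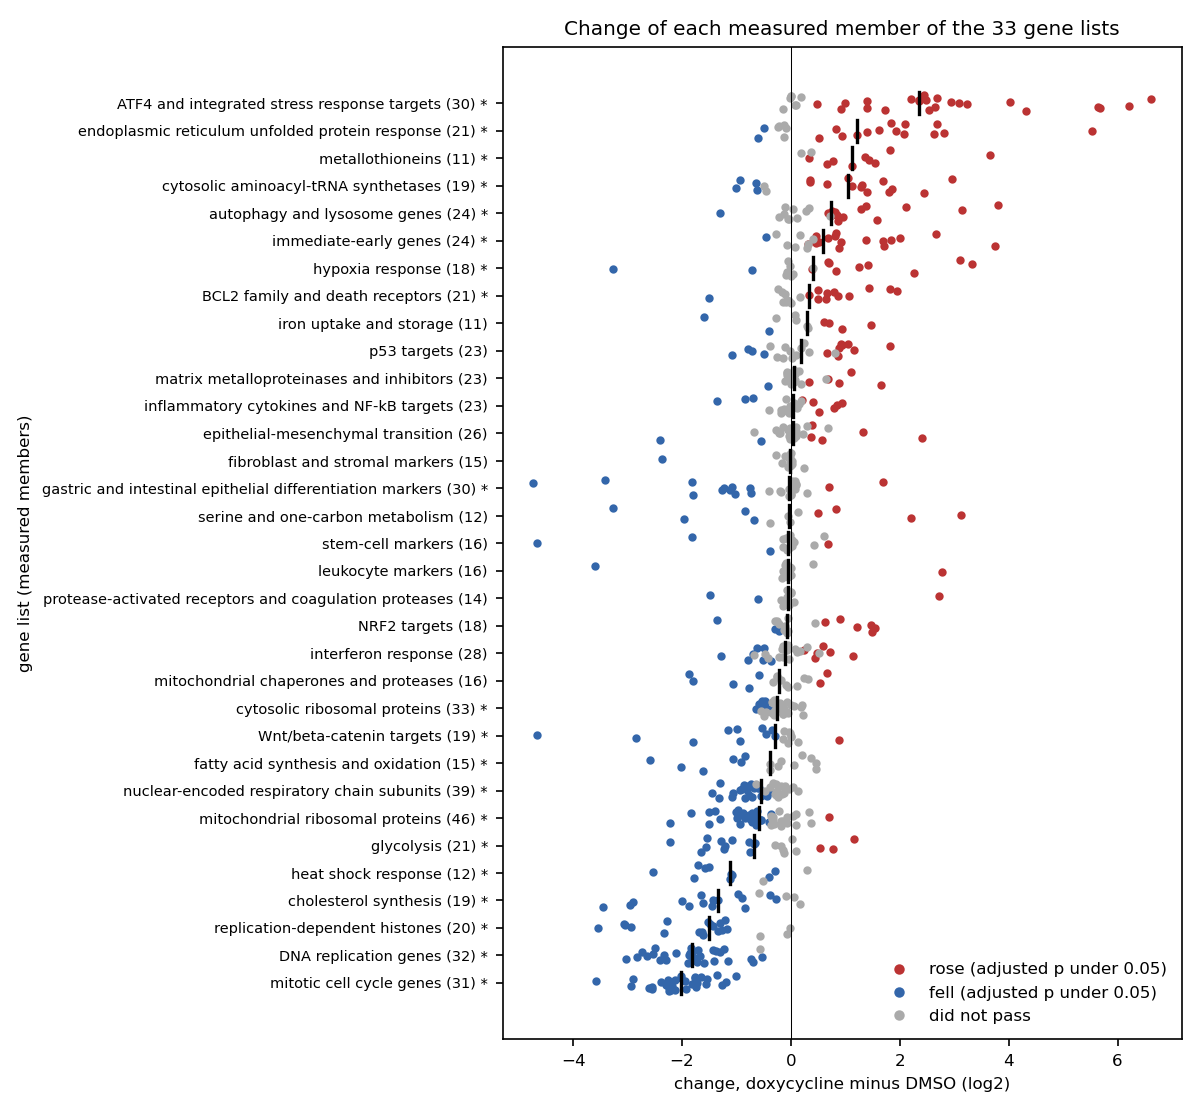
Change (doxycycline minus DMSO, log2) of each measured member of the 33 tested lists, with 1 point per gene, coloured by the gene's call, and a black bar at the list's median. An asterisk marks the 20 lists that passed camera with the preset correlation, none of which passed with an estimated correlation, and medians run from -2.03 for mitotic genes to 2.35 for ATF4 targets.

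The other 13 lists did not pass camera. Mitochondrial chaperones and proteases had 2 genes that rose and 5 that fell of 16 (3 and 8 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.0979, and 0.044 without DMSO replicate 3). TRAP1 fell by 1.87 ± 0.14 and HSPE1 by 1.80 ± 0.22, and HSPA9 rose by 0.54 ± 0.09. Of 23 p53 targets, 8 rose and 4 fell (9 and 4 adjusted over the list alone), with a median of 0.19 (adjusted p = 0.101). XPC rose by 0.92 ± 0.08 and PLK3 by 1.15 ± 0.10, and DDB2 fell by 1.08 ± 0.11. Serine and one-carbon metabolism split into 4 genes that rose and 4 that fell of 12, also adjusted over the list alone, with a median of -0.04 (adjusted p = 0.66). PSAT1 and MTHFD2, of serine synthesis and mitochondrial folate metabolism, rose by 3.13 ± 0.18 and 2.21 ± 0.12, whereas TYMS, thymidylate synthase, and MTHFD1 fell by 3.26 ± 0.19 and 1.97 ± 0.09. NRF2 targets rose in 6 and fell in 3 of 18, also adjusted over the list alone (adjusted p = 0.455), with a median of -0.07 against a mean of 0.26 and an upward test. GCLC and GCLM, of glutathione synthesis, rose by 1.54 ± 0.10 and 1.22 ± 0.15, and TKT fell by 1.36 ± 0.19.

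Interferon response genes rose in 6 and fell in 7 of 28 (8 and 9 adjusted over the list alone), with a median of -0.11 (adjusted p = 0.506). IRF7 rose by 0.71 ± 0.10 from a DMSO mean of 4.97, and IFIT3 fell by 0.69 ± 0.10. Inflammatory cytokines and NF-kB targets rose in 6 and fell in 3 of 23 (6 and 4 adjusted over the list alone), with a median of 0.04 (adjusted p = 0.675). PTGS2, cyclooxygenase 2, fell by 1.36 ± 0.13 and IL32 rose by 0.85 ± 0.11. Most members without a call lay near the median of all features, such as IL6 and CXCL8 (DMSO means 3.89 and 3.84), unlike NFKBIA (9.84). Matrix metalloproteinases and their inhibitors rose in 5 and fell in 1 of 23, also adjusted over the list alone, with a median of 0.05 (adjusted p = 0.112). ADAM17 rose by 1.66 ± 0.12 and MMP1 by 0.89 ± 0.12 from a DMSO mean of 4.37, and ADAM10 fell by 0.42 ± 0.10. Without DMSO replicate 1, doxycycline replicate 2 or doxycycline replicate 3 ADAM10 had -0.37, -0.39 and -0.41 and no call (adjusted p = 0.0742, 0.0742 and 0.0782). Iron uptake and storage genes rose in 4 and fell in 2 of 11 (5 and 2 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.191), and FTL rose by 0.93 ± 0.09 while STEAP3 fell by 1.59 ± 0.08. Epithelial-mesenchymal transition genes rose in 5 and fell in 2 of 26 (7 and 2 adjusted over the list alone), with a median of 0.03 (adjusted p = 0.31). The tight junction genes CLDN1 and OCLN rose by 2.41 ± 0.11 and 1.32 ± 0.13, and CCN2 fell by 2.40 ± 0.28 to a mean of 4.98. Some members without a call lay near the median of all features, such as FN1 and CDH2 (DMSO means 3.57 and 3.95), and others well above it, such as EPCAM (13.69). Stem-cell markers rose in 1 and fell in 3 of 16, also adjusted over the list alone, with a median of -0.05 (adjusted p = 0.336). SOX2 fell by 1.81 ± 0.16, and KLF4 rose by 0.69 ± 0.10. Protease-activated receptors and coagulation proteases rose in 1 and fell in 2 of 14, also adjusted over the list alone (adjusted p = 0.373), with a median of -0.06, a mean of 0.00 and a downward test. PLAUR, the urokinase receptor, rose by 2.71 ± 0.13 and PROCR fell by 1.49 ± 0.20.

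Markers of cells that the culture should not hold were included as 2 lists. Fibroblast and stromal markers fell in 1 of 15 and rose in 0, also adjusted over the list alone (median -0.02, adjusted p = 0.373), and the 1 was PDGFRA, a growth factor receptor, which fell by 2.36 ± 0.07. Most of the others lay near the median of all features, such as COL1A1 and LUM (DMSO means 4.42 and 3.49), though TAGLN lay at 7.22. Leukocyte markers rose in 1 and fell in 1 of 16, also adjusted over the list alone (median -0.05, adjusted p = 0.373). CD68, a lysosomal membrane protein, rose by 2.78 ± 0.22, and LYZ, which gastric epithelium also expresses, fell by 3.60 ± 0.25.

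On the 2 arrays that stood apart, the median of all tested genes deviated from the other arrays of the same group by -0.04. Histones deviated by -0.516, mitotic genes by -0.325, cytosolic ribosomal protein genes by -0.295, cholesterol synthesis genes by -0.247, immediate-early genes by -0.243, DNA replication genes by -0.225, autophagy and lysosome genes by -0.224, respiratory chain genes by -0.213, fatty acid genes by -0.212 and mitochondrial ribosomal protein genes by -0.209. Metallothioneins deviated by -0.192, interferon response genes by -0.191 and heat shock genes by -0.169. The other 20 tested lists deviated by -0.196, for serine and one-carbon metabolism, to -0.007, for stem-cell markers. The deviation exceeded the median change in size for 2 lists that passed camera, cytosolic ribosomal proteins and gastric markers, and for 6 that did not: interferon response, serine metabolism, NRF2 targets, inflammatory genes, leukocyte markers and fibroblast markers. Since the 2 arrays are in different groups, a deviation they share largely cancels in the change and mainly widens the spread. Without these 2 arrays, a comparison chosen after the data were seen, 6584 genes changed, 5497 of them shared with the 6070. In that comparison 32 of 32 DNA replication genes, 31 of 31 mitotic genes and 15 of 19 cholesterol synthesis genes fell, and 23 of 30 ATF4 targets rose. Some counts moved by more than 1.5 times: 16 in place of 7 cytosolic ribosomal protein genes fell, 3 in place of 0 fatty acid genes rose, 3 in place of 1 stem-cell marker rose, and 2 in place of 1 mitochondrial ribosomal protein gene rose, while 2 in place of 1 fell among immediate-early genes and among fibroblast markers.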

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

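The 3 tests of the arrays that stand apart and both tests against signal level were chosen after the results were seen, and leaving those 2 arrays out was added after the data were seen. Outside the tested genes, 1481 features with several gene symbols or none changed at least 2-fold (limma over all features). Of 22 features whose identifier carries the chromosome code M, 16 changed, and all 16 fell. The code equals the chromosome of the named gene for 99.69% of 22730 features, and these 22 had no single gene symbol here, so no gene is named for them. Many of them lie near 19, above the ceiling of a 16-bit scanner, where the deposited scale is least certain. The largest fall, -4.15 ± 0.44 log2 units, began from DMSO values of 16.42 to 18.02. Features with all values under 16 fell by 3.13 ± 0.71, 2.22 ± 0.15, 2.01 ± 0.14 and 0.78 ± 0.15. Changes of -0.98 and -0.16 in that range had no call.

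DMSO replicate 3 and doxycycline replicate 1 deviated together from their groups, with a correlation of 0.565 across genes, which are not independent replicates. Swapped labels are argued against, since each of the 2 arrays correlated more closely with its own group, by at least 0.0201. A stronger or weaker response along the doxycycline effect stays open: the shared deviation correlated with that effect by 0.067, but the 2 arrays were picked on the second component (r = 0.993 with the deviation, across genes), which is orthogonal to the one that carries treatment. The poly-A controls lay lowest in their group on these arrays in 7 of 8 comparisons, which a difference in target preparation would give. Controls of 1 array can move together, so the 8 comparisons are not independent and rest on 2 arrays. The limit for this test was also set after the control values had been seen. No biological explanation of the shared deviation was tested, because the design names none.

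Nuclear genes for the respiratory chain and the mitochondrial ribosome fell in 21 of 39 and 27 of 46, with 18 not passing in each and MRPS10 rising, and both lists lose their call with an estimated correlation (adjusted p = 0.37). A shift of abundant genes following signal level is argued against, since their median of -0.56 lay at percentile 0 of 10000 lists matched on mean signal. Without the 2 apart arrays the median kept 0.943 of its value, so the fall is present in the remaining arrays. The 2 arrays are in different groups and deviate together, so what they share largely cancels in the difference. The share kept therefore cannot test that shared deviation. A response of the cells to doxycycline, the difference the design gives, stays open and was not tested apart from the comparison itself.

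Zinc finger genes with the symbol root ZNF rose in 145 and fell in 33 of 534, a pattern found by looking through 34 symbol roots. Signal level is argued against, since the median of 0.09 lay at percentile 100 of 10000 matched lists. Without the 2 apart arrays the median kept 0.923 of its value, which for the reason given above cannot test their shared deviation. The family passed camera with the preset correlation (adjusted p = 0.000307) and not with an estimated one (adjusted p = 0.195), so the rise may be no more than genes that vary together.

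With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 6070 genes and the highest other 0, and 1 of the 10 splits, the real one, reached that count. For lists, the real split gave 20 and the highest other 12, with 1 of the 10 reaching 20. The other 9 splits gave 5 to 12 lists, and limma called 0 genes in them. Each of those 9 mixes both treatments within its groups. Part of the treatment difference thus stays in the comparison, and the rest widens the spread within groups. These counts therefore give no rate of false calls, for genes or for lists.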

How the results depend on the processing

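Leaving out the 2 arrays that stand apart, treating them as a block and testing protein-coding genes alone were chosen after the data were seen; the other alternatives were set before. The 20 lists passed in each of the 18 settings of arrays, features, scaling or variance model, and none reversed. In the 11 settings that count genes, other than those without 1 array, the count of changed genes lay between 5035 and 8146 with 49.1% to 53.7% rising. Without 1 array it lay between 4558 and 6001, with 46.7% to 54.2% rising and 4498 to 5430 genes shared with the 6070. The 2 apart arrays left out gave 6584 genes, and as a block 7788. The replicate numbers share no deviation in every pair (r = -0.281, 0.376 and -0.241, across genes), not every array correlated best with its own number, and the replicate block gave 5035 genes, moved no list's call and ended that of 1 gene named by the rule, RPS6 (-0.48, adjusted p = 0.0507).

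Stricter rules lowered the counts by construction: at an adjusted p under 0.01, 3892 genes passed (2001 rose, 1891 fell), and with at least a 2-fold change 1874 (919 and 955). In place of 1874 genes changed at least 2-fold, a test of all features of the file gave 3667 features, 1481 of them clusters with several symbols or none, which is not a count of genes. RPS6 and RPL34 lost their calls there (adjusted p = 0.0659 and 0.0677). Camera with an estimated correlation called 0 of the 33 lists, where the preset one called 20 and fry 27. The camera calls therefore rest on the preset form of the test. Estimates for the 20 lists ran from 0.037, for the endoplasmic reticulum unfolded protein response, to 0.639, for cytosolic ribosomal proteins. The former is near the preset 0.01, and its call was still lost (camera adjusted p = 0.178). A lost call thus does not by itself show that the genes vary together. Of 147 genes named by the rule 141 passed, and 4 lost the call in some setting (RPS6, RPL34, RPS23 and MMP10). MMP10 lost it with the 2 apart arrays left out and in no other setting (0.31 against 0.34, adjusted p = 0.074). The leukocyte marker NKG7 and the stromal marker TAGLN gained a call with the 2 apart arrays as a block (0.397 and -0.27, limma adjusted p = 0.02255 and 0.01091). NKG7 also gained one among protein-coding genes alone (adjusted p = 0.04524), and TAGLN with those arrays left out (-0.275, adjusted p = 0.03813). Of 28 further genes, named after their values were seen, 27 passed and 7 lost the call: FARSB, MYC, PDIA4, QARS1, ADAM10, SEC11A and HK2. The replicate block ended all 7 calls, HK2's there alone (0.53, adjusted p = 0.0512), a test of all features those of the other 6, and arrays centred on their median those of FARSB and MYC (adjusted p = 0.0632 and 0.0699). None of the 28 reversed. Mitochondrial chaperones passed after repeated quantile normalization and without DMSO replicate 3, and metalloproteinases and p53 targets over all features. The signal over background limits genes near the feature median of 4.09, and no scaling moved the median of all genes by more than 0.02 log2 units.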

Other observations

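All observations here were made after the data were seen. Symbols were looked through by 34 roots, 2 of the families were narrowed or widened afterwards, and 9 were picked after their values were seen, 8 described here and the ZNF genes above. The adjusted p-values cover all 35 families with at least 3 genes, 16 of which passed camera with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.195. That adjustment does not allow for a choice of roots made after the data were seen.

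The pregnancy-specific glycoprotein genes fell in 10 of 10, with a median of -3.12 log2 units (camera adjusted p = 2.49e-11, and adjusted p = 0.391 with an estimated correlation). Their near-identical sequences leave open which copies were read, and camera counts them as 10 separate genes. The 3 fibrinogen chain genes all fell, with FGA lower by 4.51 ± 0.36 and FGB by 3.56 ± 0.21, to means of 4.01 and 3.83 near the median of all features, so both falls are possible lower bounds (adjusted p = 0.000547, and adjusted p = 0.474 with an estimated correlation). Genes of protein translocation and vesicle coats with SEC names rose in 14 and fell in 1 of 20, with a median of 0.90 (adjusted p = 1.55e-05, and adjusted p = 0.539 with an estimated correlation). SEC24D rose by 1.82 ± 0.10 and SEC31A by 1.80 ± 0.09, and SEC11A fell by 0.49 ± 0.12. Among single arrays, its call outlasted only the loss of DMSO replicate 3, with -0.51 to -0.40 and adjusted p between 0.0587 and 0.081 without each of the other 5 arrays. Small proline-rich protein genes, of the epidermal cornified envelope, rose in 5 of 11 and fell in 0 (adjusted p = 0.000928, and adjusted p = 0.566 with an estimated correlation). SPRR2D rose by 3.94 ± 0.29 from a DMSO mean of 4.15 to 8.09, and since the DMSO mean lies near that median the rise is a possible lower bound too.

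Proteasome subunit genes fell in 14 of 36 and rose in 0, with a median of -0.32 (adjusted p = 0.000928, and adjusted p = 0.736 with an estimated correlation), and PSMD1 fell by 0.97 ± 0.09. Small nuclear RNA genes and copies with the root RNU fell in 62 and rose in 13 of 213 (adjusted p = 0.00123, and adjusted p = 0.659 with an estimated correlation). H/ACA small nucleolar RNA genes fell in 16 and rose in 1 of 64 (adjusted p = 0.00859, and adjusted p = 0.736 with an estimated correlation), and on the 2 arrays that stood apart their median deviated by -0.25. HLA genes rose in 6 and fell in 0 of 27, and the family did not pass (adjusted p = 0.244), with HLA-B higher by 0.78 ± 0.15.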
